A study of Mus musculus with 2 samples.

How the data were processed

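Whole lungs of wild type and TAZ-deficient mouse embryos at E15.5 (the embryonic day) were profiled with an Affymetrix one-colour mouse expression array. TAZ, encoded by Wwtr1, is a transcriptional coactivator that is held back by the Hippo kinase cascade and that binds TEAD transcription factors. Per the series' design text, 4 total RNA samples were mixed for each group, so that each group is 1 pool on 1 array. Biotin-labelled cRNA was made from the pooled total RNA after priming on the poly(A) tail, per the labels' protocols.

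The deposited table holds 1 intensity value per probe set and array. GCOS and MAS5 are named in the submitters' processing notes, with no version. The intensity values deposited by the authors are linear, carry 1 decimal and are never negative. On each array their mean after removal of the lowest and highest 2% was 100.001, so each array had been scaled as a whole to a common mean. No detection call was used here. How the TAZ deficiency was made, the position of the probes relative to the disrupted part of the gene and the genome build behind the probe design are not given in the sources used here.

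The table had 45101 probe sets, of which 64 were control probe sets. The platform annotation named 1 gene for 34945 of the other probe sets and several genes for 932, and it did not list 9160. Probe sets with several genes or none were not assigned to a gene. Symbols were updated through the Entrez identifier to the GRCm38.p6 RefSeq annotation for 34741 probe sets. The 34945 probe sets stood for 18193 genes. A gene with several probe sets was represented by the probe set with the highest mean log2 intensity of the 2 arrays.

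Values were used on the deposited scale. A floor was set at the median of all non-control values, 15.2 signal units, and values below it were set to 15.2 before the log2 ratio of TAZ-deficient over wild type was taken. A gene was called measured when its signal was above the floor on either array, which held for 12032 genes. Where one of the 2 signals was at or below the floor, the fold is a lower bound and is written as "at least". The floor understates the fold only for such genes, and leaves the fold of genes with both signals above it unchanged.

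With 1 array per group there is no spread between replicates, and no test, p-value, SD or standard error can be given for any difference. The number of arrays limits the precision of every value. Genes were instead named by a rule of size. A difference of at least 2-fold was counted across all measured genes, and a difference of at least 1.5-fold within gene lists. The rule named Wwtr1, then up to 12 genes with the largest and up to 12 with the lowest ratio among genes at least 2-fold different whose other probe sets above the floor had the same sign, leaving out clone names. It also named every measured YAP/TAZ target, the housekeeping and sex-linked genes, and up to 4 genes per other list among those at least 1.5-fold different, or otherwise the 2 brightest. Further members of a list, the genes next to Wwtr1, Borcs7 and Slc30a1 are given as examples chosen after their values were seen.

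The 37 gene lists, with 624 entries, cover Hippo signalling, lung cell types, neighbouring tissues, signalling responses, stress, cell cycle, housekeeping and sex-linked genes. They were written from textbook knowledge before the data were examined, as were the floor, the thresholds, the naming rule and the alternatives. Of 610 distinct genes, 567 matched a probe set naming that gene alone, and 453 were measured. The median log2 ratio of each list was placed among 10000 random lists of the same size, drawn from 20 bins of mean log2 signal, or among 2000 such lists under each alternative. The position describes these 2 arrays and is no test of the genotype, since genes are not independent replicates. Of 37 lists, 1.85 would lie outside the central 95% by chance if genes were independent, and lists that share co-regulated genes can exceed that.

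The only error that 2 arrays allow is the disagreement between probe sets of one gene. Over 5637 genes with at least 2 probe sets above the floor, the log2 ratios of the brightest and second brightest differed with an SD, divided by the square root of 2, of 0.20. It was 0.13 for the 2418 genes with both probe sets above 106.3 signal units (the 75th percentile) and 0.24 for the other 3219. This value holds no variation between embryos, pools, labelling reactions or arrays.

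The counting rule and the list comparison were tested on simulated data. A pair of arrays with the real mean signals of 18193 genes, the probe set noise above and 50 changed genes per fold size gave 2-fold calls for 94% of genes changed 3-fold and for 58% of genes changed 2-fold. It gave none for genes changed 1.5-fold or not at all. For unchanged genes that outcome was fixed in advance, because the simulated noise was within-array only and small next to 2-fold. It gives no rate of false calls between real pools. Of 300 random lists of 18 genes, 3% lay outside the central 95%, and of 100 lists shifted by 0.2 on the log2 scale, 99% did. Both outcomes follow largely from the design, since these lists were drawn from the same measured genes and hold no co-regulated sets. They check the calculation only.

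Alternatives were median centring, quantile normalization (limma 3.58.1 in R 4.3.3), an intensity-dependent loess with a span of 0.3, floors at the 25th and 75th percentile, a pseudocount equal to the floor in its place, the median over all probe sets of a gene, only probe sets without the suffixes of shared or cross-hybridising sets, thresholds of 1.5-fold and 3-fold, and a call by 2 probe sets. Other steps used Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6.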

Results

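The data comprised 2 arrays of whole lung at E15.5, 1 of a pool of 4 wild type RNA samples and 1 of a pool of 4 TAZ-deficient RNA samples, wild type and TAZ-deficient mice being littermates. The comparison asks which transcripts differ between lungs with and without TAZ before birth. Signals ran from 0 to 5348.1 on the wild type array and from 0 to 5541.4 on the TAZ-deficient array, with medians of 15.2 and 15.1. Across the 11391 genes above the floor of 15.2 on both arrays, log2 signals correlated with Pearson's r of 0.99, a value across genes, which are not independent replicates. Since each group was 1 pool on 1 array, no difference below has a replicate check.

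Wwtr1, the gene that encodes TAZ, was close to background in the TAZ-deficient pool. Its brightest probe set read 791.2 in wild type and 11.3 in TAZ-deficient lung, at least 52.1-fold lower. The other 2 probe sets read 222.9 against 6.4 and 176.9 against 3.9, at least 14.7-fold and 11.6-fold lower. All 3 probe sets thus followed the labels of the arrays. The bound depends on the floor, the log2 ratio of the brightest probe set being -5.70 here and -2.90 with the floor at the 75th percentile. No other gene among the 12032 measured had a lower ratio.

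With the floor at the median signal, 14 genes in TAZ-deficient lung were at least 2-fold higher and 9, Wwtr1 included, at least 2-fold lower, and 81.4% of measured genes were within 1.2-fold. The counts depended on the floor, being 249 higher and 355 lower with the floor at the 25th percentile and 2 and 1 at the 75th. At 1.5-fold the counts were 153 higher and 176 lower, and of the 88 such genes with a second probe set above the floor, it had the same sign in 55 and was itself 1.5-fold different that way in 7. The embryonic globins formed the brightest group among the genes that were higher. Hbb-y, the embryonic beta-like globin, read 926.0 in wild type and 2825.8 in TAZ-deficient lung (3.05-fold), and Hba-x, the embryonic alpha-like (zeta) globin, read 113.8 and 409.2 (3.60-fold). Hbb-bh1, another embryonic beta-like globin, read 19.9 and 61.7 (3.10-fold). All 3 probe sets of Hbb-y and of Hbb-bh1 had log2 ratios between 1.52 and 1.73. These beta-like genes are similar in sequence, so that their probe sets can share signal.

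The metallothioneins, small metal-binding proteins induced by zinc and glucocorticoids, were the lowest after Wwtr1. Mt2 read 212.4 in wild type and 25.1 in TAZ-deficient lung (8.46-fold lower), and Mt1 read 198.6 and 66.6 (2.98-fold lower). The Mt1 probe set has the suffix of a set shared between transcripts, and the second Mt1 probe set was below the floor on both arrays. Dynlrb2, a dynein light chain of motile cilia, was 2.35-fold lower (120.3 and 51.1). Upk3a, a uroplakin, was 2.25-fold lower (35.3 and 15.7), and the zinc finger gene Zfp13 at least 2.13-fold lower (32.3 and 14.9). Borcs7 was 2.34-fold lower by its brighter probe set, while its other probe set read 54.1 and 55.1.

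The remaining genes at least 2-fold higher were dim. Ces5a, a carboxylesterase, read 14.2 and 108.5 (at least 7.14-fold), and Zap70, a T cell kinase, read 14 and 95.1 (at least 6.26-fold), but the other 2 probe sets of each gene were below the floor on both arrays. Rab6b was 2.51-fold higher by 1 of 4 probe sets, the only one above the floor. Fbxl16, Dok7, Dgkk, Tnfaip6, Extl1 and Psg23 were between 2.02-fold and 2.13-fold higher, with no signal above 51.4, the ratio of Extl1 being a lower bound. No other probe set above the floor was found for 11 of the 14 genes higher and 5 of the 9 lower. Of the 7 genes that had one, the second brightest probe set had the same sign in 5 and was also 2-fold different in 3, which were Wwtr1, Hbb-y and Hbb-bh1.

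**Figure D1:**
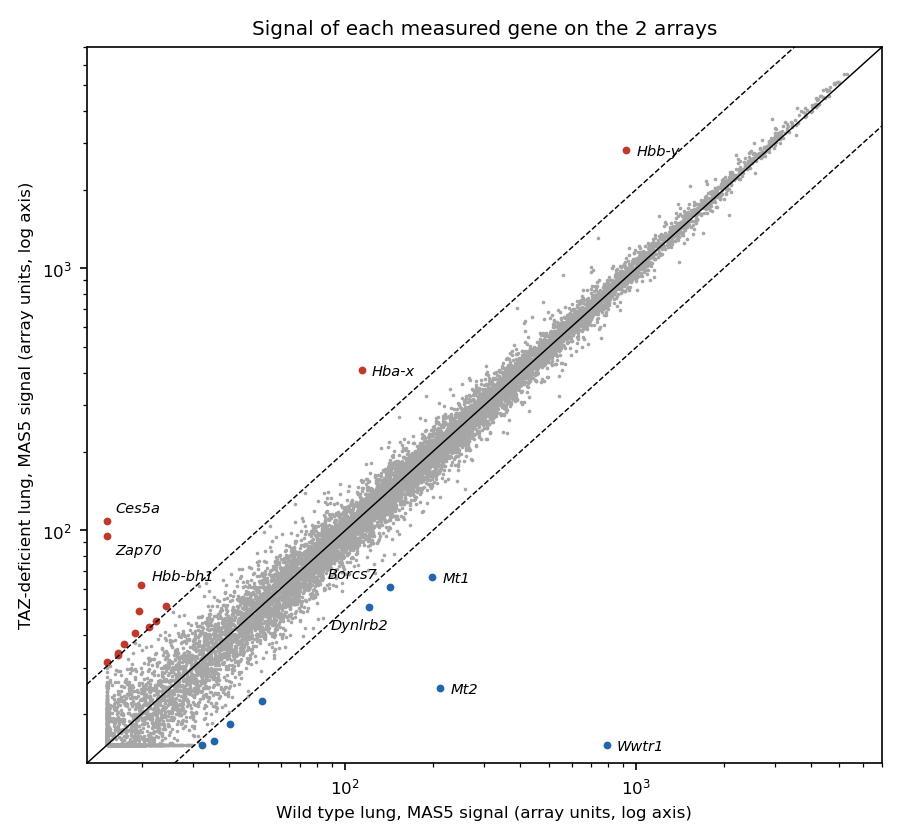
MAS5 signal of each of the 12032 measured genes in wild type (x axis) and TAZ-deficient lung (y axis), in array units on log axes, with values below 15.2 drawn at 15.2. The solid line marks equal signal and the dashed lines 2-fold differences; the 14 genes at least 2-fold higher are red and the 9 at least 2-fold lower blue, with Wwtr1 at 791.2 against 11.3 and Mt2 at 212.4 against 25.1 far below the line.

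Genes known as targets of YAP and TAZ differed little as a group. Of 27 measured members, Crim1, a transmembrane regulator of growth factors, was the only one at least 1.5-fold lower (1.51-fold, 30.6 and 20.3) and Myof the only one at least 1.5-fold higher (1.72-fold, 32.6 and 56.2), and the second probe set of Crim1 had the opposite sign. The matricellular genes Ccn1 (CYR61) and Ccn2 (CTGF), the best known targets, were 1.40-fold (139.8 and 100.0) and 1.35-fold lower (215.5 and 159.1), and Gadd45b was 1.27-fold lower. The probe sets used for Ccn1 (1 of 4) and Myof (1 of 2) have the suffix of a cross-hybridising and of a shared set. Igfbp3 was 1.31-fold higher. Ccnd1 was 1.21-fold higher at its brightest probe set but lower at its other 2 (714.4 and 691.5, 269.1 and 235.5). Foxf2 (1.15-fold), Thbs1 (1.10-fold), Dock5 (1.08-fold), Amotl2 (1.04-fold), Fjx1 (1.04-fold) and Nuak2 (1.02-fold) had positive ratios. Gadd45a (1.16-fold), F3 (1.14-fold), Nt5e (at least 1.09-fold), Axl (1.07-fold), Asap1 (1.06-fold), Slc7a5 (1.06-fold), Tgfb1 (1.06-fold), Arhgef17 (1.05-fold), Ajuba (1.05-fold), Tgfb2 (1.04-fold), Birc5 (1.03-fold), Lats2 (1.01-fold), Rbms3 (1.01-fold) and Ptpn14 (1.00-fold) had negative ones. Lats2 and Ptpn14 had positive ratios under quantile normalization and loess, and Ptpn14 also under median centring. In all, 18 of 27 ratios were below 0 on the deposited scale. The median log2 ratio was -0.06, and 9.92% of random lists had a lower one. The median lay inside the central 95% of random lists.

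As a group, the other components of the Hippo pathway were close to wild type signal. Single members differed in both directions, Amot being 1.38-fold higher (102.5 and 141.5) and Vgll3 1.36-fold lower (44.0 and 32.4). Yap1, the paralogue of TAZ, read 646.2 in wild type and 681.1 in TAZ-deficient lung, and the DNA-binding partner Tead1 read 211.2 and 211.3. Apart from Wwtr1, the only one of 26 measured members at least 1.5-fold different was the cadherin Fat4 (1.51-fold higher, 71.8 and 108.3), whose second probe set read 66.6 and 69.6. The list's median log2 ratio was -0.02, with 48.5% of random lists lower.

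Genes of glycolysis and of the response to low oxygen were higher in TAZ-deficient lung, all 18 measured members having a positive ratio. Slc2a1, the glucose transporter GLUT1, was 1.51-fold higher (416.0 and 629.5), with log2 ratios of 0.60, 0.54 and 0.45 at its 3 probe sets. Ankrd37, a hypoxia-induced ankyrin repeat gene, was 1.57-fold higher (95.8 and 150.6). The mitophagy receptor Bnip3 (1.49-fold), the collagen prolyl hydroxylase subunit P4ha1 (1.49-fold), hexokinase 2 (Hk2, 1.40-fold), aldolase A (Aldoa, 1.33-fold) and lactate dehydrogenase A (Ldha, 1.19-fold) were below 1.5-fold. The median log2 ratio was 0.31 (1.24-fold), and 100% of the 10000 random lists had a lower median, the highest share of the 37 lists.

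**Figure D2:**
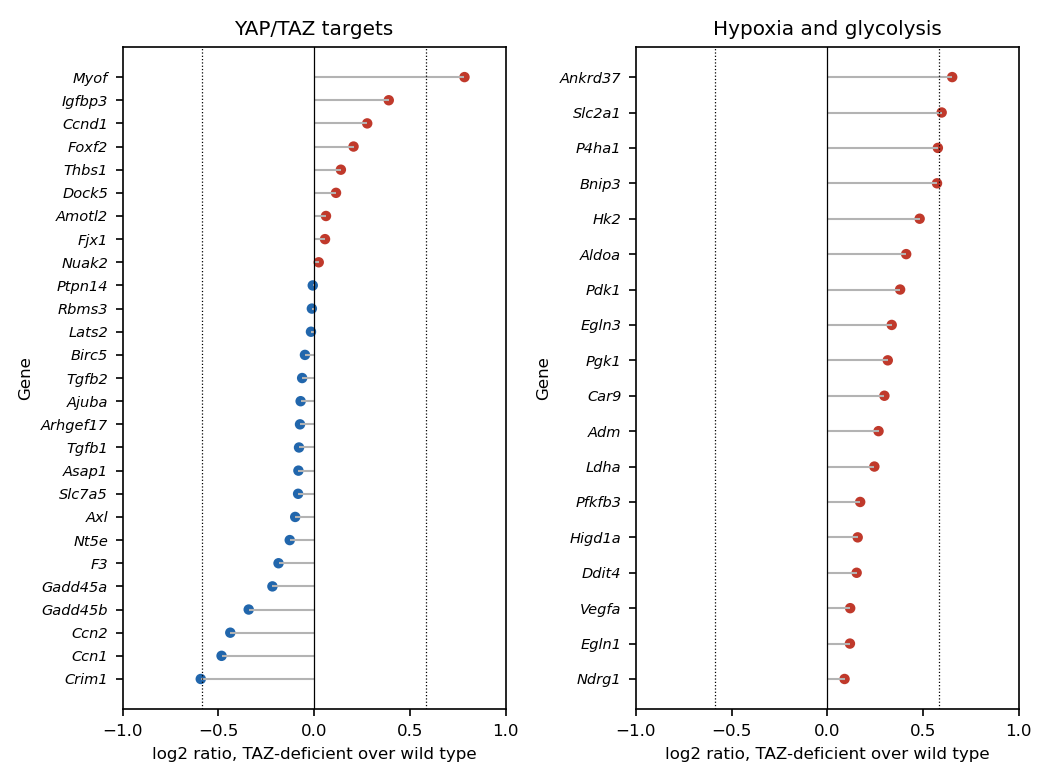
The log2 ratio of TAZ-deficient over wild type signal (x axis) for each measured gene (y axis) of the YAP/TAZ target list, left, and of the hypoxia and glycolysis list, right; dotted lines mark 1.5-fold. The 18 hypoxia and glycolysis genes all lie above 0, whereas 18 of the 27 YAP/TAZ targets lie below 0, with Ccn1 and Ccn2 among the lowest.

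Among epithelial lists, the median of the distal epithelium and type 2 cell list was above 0 and that of the type 1 cell list below 0. Of the distal epithelium and type 2 cell list, 22 genes were measured and only Scd1, a fatty acid desaturase, was 1.5-fold different (1.52-fold higher, 50.6 and 76.8; second probe set 24.6 and 25.8). Surfactant protein C (Sftpc) read 4142.5 and 4121.5, surfactant protein B (Sftpb) 635.5 and 706.4, and the lamellar body transporter Abca3 212.1 and 232.5. The list's median log2 ratio was 0.09, above 99.7% of random lists, but it lay inside their central 95% under 5 of 8 alternatives, among them quantile normalization, where it was 0.05, and the median over probe sets, where it was 0.022. No type 1 cell gene was 1.5-fold different, and 14 of 17 had negative ratios. At this floor Hopx (1.36-fold), Akap5 (1.31-fold) and Emp2 (1.28-fold) were the lowest, with Col4a3 at least 1.27-fold lower (19.3 and 11.2). The bright members Cav1 (2429.2 and 2539.1) and Igfbp2 (1134.3 and 1190.1) were slightly higher. The median was -0.12, with 0.58% of random lists lower, and -0.24 with the floor at the 25th percentile.

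Of 11 measured genes of ciliated cells, 4 were at least 1.5-fold lower and 0 higher, and 6 ratios were negative and 5 positive. The 4 lower ones were Dynlrb2 (2.35-fold), Cfap126 (1.78-fold, 51.5 and 29.0), the multiciliogenesis cyclin Ccno (1.55-fold, 69.7 and 45.1) and Rsph1 (1.51-fold, 29.3 and 19.4). Foxj1, the regulator of motile ciliogenesis, read 32.2 and 32.6. The median of the list was -0.26, with 0.32% of random lists lower, and -0.097 and -0.048 with floors at the 25th and 75th percentile, the latter on 4 genes, where it lay inside their range. In the club and proximal airway list none of 8 measured genes was 1.5-fold different. The secretoglobin Scgb3a2 (1408.5 and 1057.4) was 1.33-fold lower and Cldn10 (406.4 and 368.9) 1.10-fold lower, and the median was -0.20, with 0.53% of random lists lower. It was -0.080 with the floor at the 25th percentile and -0.15 on 3 genes without shared probe sets, both inside the range of random lists. Neuroendocrine genes (4 measured, Ddc 163.4 and 160.3, Uchl1 147.2 and 153.3) had a median of -0.10. General adhesion and polarity genes had a median of 0.08, above 98.8% of random lists, with none of 18 at 1.5-fold; the brightest, Epcam and Tjp1, read 1287.4 and 1335.8, and 1094.8 and 1114.6. The 11 cilia and cystic kidney genes had a median of -0.10 and none at 1.5-fold (Dync2li1 261.1 and 258.3, Kif3a 130.4 and 133.0).

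Smooth muscle genes were lower, with 13 of 14 measured members below 0. Synpo2, a Z-disc-associated actin-binding protein, was 1.55-fold lower (97.2 and 62.9) and calponin 1 (Cnn1) was just over 1.5-fold lower (118.6 and 79.0). Smooth muscle myosin (Myh11) was 1.41-fold and Tagln 1.28-fold lower, while smooth muscle actin (Acta2) read 2749.2 and 2701.5. The median log2 ratio was -0.26, and 0% of random lists had a lower one; it was -0.16 with the floor at the 75th percentile. Heart muscle genes were lower as well. Of 7 measured members, 7 were below 0 and 3 at least 1.5-fold lower, namely Myl7 (1.81-fold, 83.6 and 46.2), Myh7 (1.62-fold, 24.9 and 15.4) and Tnnt2 (1.52-fold, 30.6 and 20.1), with a median of -0.46 and 0.03% of random lists lower. Of 3 skeletal muscle genes, Ckm was at least 1.53-fold lower (23.3 and 10.6), and the median was -0.05.

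The medians of the mesenchyme, cartilage, elastic fibre and collagen, and pericyte lists lay inside the central 95% of random lists, and that of the mesothelium list above it. Gli1, a transcription factor and readout of hedgehog signalling, was 1.62-fold lower (64.7 and 40.0) and the only one of 18 mesenchyme genes at 1.5-fold (median -0.06, 4.06% of random lists lower). Matn3 was the only one of 13 cartilage genes at 1.5-fold (1.83-fold lower, 33.5 and 18.3; median 0.08, mean -0.01). None of 23 elastic fibre and collagen genes was 1.5-fold different (median 0.00, mean -0.03), and the median was below 0 under quantile normalization and loess. Their log2 ratios ran from -0.56 (Fbln5) to 0.42. The brightest, Col3a1 and Col1a2, read 3422.8 and 3524.0, and 1829.7 and 1868.5, both below wild type under quantile normalization and loess. Pericyte genes had a median of 0.01 (Pdgfrb 510.1 and 523.6, Abcc9 235.0 and 212.8). Mesothelial genes, 9 measured, had a median of 0.18, above 99.2% of random lists, with none at 1.5-fold and the bright members Krt19 (490.8 and 441.9) and Upk3b (239.9 and 280.3) in opposite directions; on the 3 genes left with the floor at the 75th percentile the median was 0.12, inside the range.

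Vascular and blood cell lists differed little apart from the globins. None of 22 endothelial genes was 1.5-fold different (median -0.03; the apelin receptor Aplnr 2905.5 and 2944.2, Ednrb 985.6 and 920.2), nor any of 4 lymphatic genes (median 0.10; Lyve1 446.3 and 469.8, Mmrn1 238.7 and 276.5). Of 18 leukocyte genes, S100a8, a neutrophil calcium-binding protein, was 1.54-fold higher (86.4 and 133.4). The macrophage complement genes C1qa, C1qb and C1qc were 1.29-fold, 1.37-fold and 1.31-fold lower, and the list's median was -0.09, with 12.1% of random lists lower. Of 7 measured erythroid genes the 3 embryonic globins were higher and Trim10 was 1.76-fold lower (80.6 and 45.9), so that the median was 0.02 and the mean 0.54, the median being below 0 under quantile normalization and loess.

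**Figure D3:**
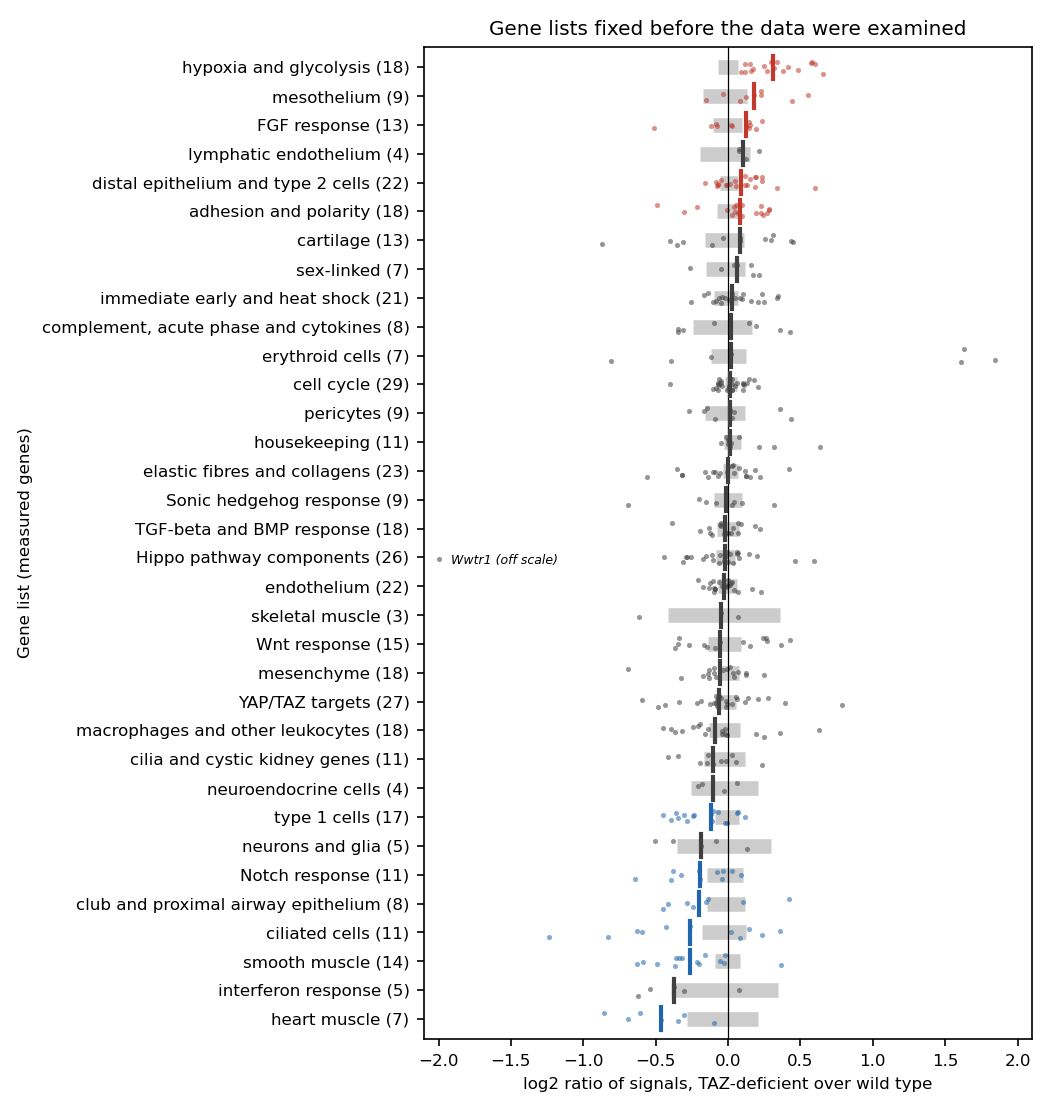
Log2 ratio of TAZ-deficient over wild type signal (x axis) for the measured members (points) of each gene list with at least 3 measured genes (y axis, number measured in brackets), with the list median as a vertical bar and the central 95% of medians of 10000 matched random lists in grey. Red and blue lists lie above and below that range; hypoxia and glycolysis has the highest median (0.31) and heart muscle the lowest (-0.46), and Wwtr1 is drawn at the left edge, off scale.

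Of the signalling lists, the Notch response median lay below the central 95% of random lists and the FGF response median above it. Heyl, a Notch target of vascular smooth muscle, was 1.57-fold lower (185.2 and 118.3), with negative ratios at all 3 probe sets, and the glycosyltransferase Lfng was 1.32-fold lower and the target Hey1 read 99.4 and 79.5. Of 11 measured members 9 were below 0, and the median was -0.19, with 0.64% of random lists lower. The FGF response list had a median of 0.12, above 99.1% of random lists, and a mean of 0.03, with none of 13 at 1.5-fold (Etv5 1420.4 and 1620.5, Fgfr2 688.5 and 748.8). Ratios were positive for 9 genes and negative for 4, the largest in size being that of Il17rd (1.43-fold lower, 70.5 and 49.4). The list's median lay inside the range of random lists under quantile normalization (0.10), with the median over probe sets (0.00) and without shared probe sets (0.08). Medians were -0.05 for Wnt response (mean 0.0036; Wnt7b 318.3 and 375.4, Sfrp2 260.6 and 206.4), -0.02 for TGF-beta and BMP response (Id2 1389.5 and 1580.5, Tgfbr2 1032.5 and 1083.8) and -0.01 for Sonic hedgehog response, which shares Gli1. Immediate early and heat shock genes had a median of 0.03 (Hspa8 4077.6 and 4214.6, Hsp90aa1 2675.1 and 2862.2). Interferon response genes had a median of -0.37 on 5 dim genes, with Bst2 1.54-fold lower (57.8 and 37.6) and 3.18% of random lists lower. Complement and cytokine genes had a median of 0.02 (Cxcl12 304.8 and 284.9, Ccl2 33.6 and 45.1). None of 29 cell cycle genes was 1.5-fold different, with a median of 0.02 that was below 0 under quantile normalization and loess (Pcna 3015.4 and 3034.4, Mcm7 1787.3 and 1823.4).

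Few genes of the liver, thymus, thyroid and oesophagus were measured, and those were close to the floor. Of the liver list only albumin was measured (Alb 15.3 and 10.7), of the thymus list only Cd8a (19.6 and 21.3), and of the thyroid and oesophagus list Krt6a (17.2 and 7.2) and Cnfn (17.3 and 10.4), with a median of -0.18. The 5 measured neural genes had a median of -0.19 (Gap43 51.4 and 48.5, Stmn2 46.1 and 32.5).

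Sex-linked transcripts and control probe sets were compared between the pools. Xist, expressed from the inactive X chromosome, read 305.1 and 253.9, and the Y-linked genes Eif2s3y, Uty and Kdm5d read 91.6 and 88.7, 64.4 and 72.4, and 58.2 and 60.8. The X-linked genes Kdm6a, Eif2s3x and Kdm5c were 1.16-fold, 1.03-fold and 1.12-fold higher, Eif2s3x being lower under quantile normalization, and the median log2 ratio of the sex-linked list was 0.06. The ratio of 3' to 5' control probe sets was 1.23 and 1.21 for Actb, 0.79 and 0.82 for Gapdh, and 2.63 and 2.56 for Tfrc. The 3 control probe sets for 18S ribosomal RNA were 1.74-fold, 1.88-fold and at least 2.38-fold higher on the TAZ-deficient array. Hybridisation spikes were 1.02-fold to 1.19-fold higher on the TAZ-deficient array (12 probe sets). Among housekeeping genes Tfrc, the transferrin receptor, was 1.55-fold higher (479.1 and 744.3), Pgk1, also a member of the hypoxia list, 1.24-fold and Sdha 1.16-fold higher, while Actb (3600.0 and 3599.5), Tbp, Hprt, B2m, Rpl13a, Ywhaz, Gusb and Eef1a1 had log2 ratios between -0.05 and 0.07. The median of the housekeeping list was 0.01, and below 0 under quantile normalization and loess.

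Genes near Wwtr1 were compared because DNA linked to a mutation can differ in strain between mutant and wild type littermates. Within 20 Mb of Wwtr1 on chromosome 3 of the GRCm38.p6 annotation, 0 of 86 other measured genes were 2-fold different, against 22 of 11929 elsewhere (0.18%). With so low a share elsewhere, a count of 0 among 86 was likely in any case, so it could not decide whether linked DNA matters. At 1.5-fold, a size that was not planned for this comparison, the counts were 7 of 86 (8.14%) and 321 of 11929 (2.69%).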

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

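Nothing in this part was tested, and no biological explanation was tested; the items are probe sets outside the gene comparison whose signal was higher on the TAZ-deficient array, with the counts of lower ones beside them. The 3 control probe sets for 18S ribosomal RNA, which lacks the poly(A) tail used for priming, were 1.74-fold (28.0 and 48.7), 1.88-fold (16 and 30) and at least 2.38-fold (12.5 and 36.2) higher, all at low signal. Among the 9160 probe sets for which no gene was listed, 7 were at least 2-fold higher and 5 at least 2-fold lower in TAZ-deficient lung. The brightest of the 7 read 97.6 and 226.3 (2.32-fold), and the brightest of the 5 read 221.7 and 102.4. Of the 932 probe sets that name several genes, 2 were at least 2-fold higher and 1 at least 2-fold lower.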

How the results depend on the processing

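No alternative here was added after the results were seen. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. The number of genes at least 2-fold different depended on the floor: with the floor at the 25th percentile (4.3 signal units) 249 genes were higher and 355 lower, and at the 75th percentile (106.3) 2 were higher (Hba-x and Hbb-y) and 1 lower (Wwtr1), fewer by construction because both signals are raised to the floor. A pseudocount gave 7 higher, the median over probe sets 8 higher and 5 lower, a 1.5-fold threshold 153 and 176, a 3-fold threshold 5 and 2, and a call by 2 probe sets 2 and 1. The log2 ratio of Wwtr1 was -5.70 and became -6.13 and -2.90 with the floors at the 25th and 75th percentile, -4.93 with the pseudocount and -3.87 as the median of its probe sets. With the floor at the 25th percentile list medians became -0.097 (ciliated cells), -0.080 (club and proximal airway), -0.33 (heart muscle) and -0.24 (type 1 cells). With the floor at the 75th percentile they became -0.048 (ciliated cells), -0.34 (heart muscle, on 1 gene) and -0.16 (smooth muscle), and with the pseudocount -0.33 (heart muscle). The median over probe sets gave 0 for FGF response, 0.022 for distal epithelium and -0.20 for smooth muscle. Leaving out shared probe sets gave -0.34 for heart muscle, -0.36 for smooth muscle and -0.17 for type 1 cells. Apart from the floors and the pseudocount, the cause of these moves was not tested. The lists hypoxia and glycolysis (0.28 to 0.34), smooth muscle, heart muscle, type 1 cells, Notch response, and adhesion and polarity lay outside the central 95% of random lists under 8 of 8 alternatives, mesothelium under 7, ciliated cells and club and proximal airway under 6, FGF response under 5 and distal epithelium under 3, whereas the YAP/TAZ targets did so under 0 of 8. All 8 alternatives rework the same 2 arrays, so agreement of a list across them is no replicate check. For heart muscle, 1 of the 8 rested on 1 gene. Of 330 values that alternatives gave for the 46 named genes at least 1.5-fold different, 325 had the same sign, 5 were 0 and 0 had the other sign. Those at 0 were medians over probe sets, most of them below the floor (Ces5a, Zap70, Rab6b, Synpo2 and Tm4sf1). Floors and the pseudocount cannot reverse a sign and the rescalings were small, so this agreement was largely fixed in advance. Between probe sets, the sign agreed for 55 of 88 genes at 1.5-fold. Median centring, quantile normalization and loess moved the median log2 ratio of all measured genes from -0.01 to between -0.01 and 0.00. Signal over background limits the dim genes: 11 of the 14 genes higher and 4 of the 9 lower had no signal above the 75th percentile.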

Other observations

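The tests on other erythroid genes, Hba-x, surfactant genes, immediate early genes, liver genes and glucocorticoid targets were chosen after the result was seen, as were the windows on other chromosomes and the choice of the 7 genes named next. Near Wwtr1, the 7 genes at least 1.5-fold different were Tm4sf1, Bche and Rarres1, which were 1.80-fold, 1.70-fold and at least 1.52-fold lower, and Intu, 2610316D01Rik, Frem2 and Fat4, which were 1.89-fold, 1.58-fold, 1.51-fold and 1.51-fold higher. Tm4sf1, a tetraspanin-like membrane protein gene (258.9 and 144.2), is the measured gene next to Wwtr1. Of 9791 overlapping windows of 86 measured genes on the other chromosomes, 20 (0.20%) held as many genes at 1.5-fold, the highest number being 7. The windows were not matched on signal. Support by other probe sets was weak, the second probe set of Fat4 and the median over the probe sets of Tm4sf1 differing little. Of 88 genes at 1.5-fold with a second probe set above the floor, across all chromosomes, 7 repeated at 1.5-fold in it.

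The embryonic globins Hba-x, Hbb-y and Hbb-bh1 were 3.05-fold to 3.60-fold higher in the TAZ-deficient pool. More blood of every kind would have raised the other erythroid genes too, but Alas2, Slc4a1, Car2 and Trim10 had a median log2 ratio of -0.26 (range -0.81 to 0.02). For these 4 genes that argues against it as the whole cause. Car2 was the brightest of them (1693.6 and 1720.6), and whether its signal came from blood was not tested. Alas2 (-0.12), Slc4a1 (-0.40) and Trim10 (-0.81) were all below 0. Hemgn, Epb42, Klf1, Rhag, Gata1 and Car1 were below the floor on both arrays. Tfrc, outside the erythroid list, went the other way (1.34-fold to 1.49-fold higher at its control probe sets). The adult globins could not be compared. The probe set of Hba-a1 was below the floor on both arrays (6.1 and 6.5), and Hbb-b1 had no probe set naming it alone. Cross-hybridisation among beta-like globins does not reach Hba-x, of the alpha cluster, whose log2 ratio was 1.85. Younger embryos in the TAZ-deficient pool could give more embryonic globin, and would lower the surfactant and type 2 genes, which rise with age. The predicted fall in each of 7 such genes was not seen. Their median log2 ratio was 0.058, and they went both ways (-0.16 to 0.15). The bound set against younger embryos required each gene to be higher in the TAZ-deficient pool. Pools of equal age would not give that, so the test could not exclude younger embryos. The lower medians of the type 1 (-0.12), club and proximal airway (-0.20) and ciliated cell (-0.26) lists go in the direction of younger or delayed lungs. However, the airway and ciliated medians lay inside the range of random lists under 2 of 8 alternatives each, and 5 of 11 ciliated genes were positive. The labels give E15.5 for both pools and call the animals littermates. The distal progenitor genes Sox9 and Mycn, picked after their values were seen, were 1.18-fold higher each. In their list 14 of 22 measured genes were positive, among them the type 2 genes Sftpb (1.11-fold) and Abca3 (1.10-fold), so it gives no clear direction of age. Younger embryos and an effect of TAZ deficiency, on lung maturation or on the primitive red cell lineage, both remain open.

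Hypoxia and glycolysis genes were higher in the TAZ-deficient pool, with a median log2 ratio of 0.31. Noise of single probe sets would not repeat in second probe sets of the same genes, yet 11 of 12 were positive, with a median log2 ratio of 0.24. A second list of 27 measured hypoxia and glycolysis genes, none of them in the first, had a median of 0.16, above 100% of 10000 random lists, with 21 of 27 positive, which is consistent with a broader hypoxia response; it was written with some bright genes of high ratio already seen, and a wrong symbol match in it was corrected after its median was seen. A delay before freezing could also raise such genes; immediate early and heat shock genes had a median of 0.026, which does not exclude it. Whether genotype, handling or other differences between the 2 pools account for it cannot be told apart with 1 array each.

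Mt2 and Mt1 were 8.46-fold and 2.98-fold lower in the TAZ-deficient pool. Liver, which is rich in metallothionein, would bring albumin and other liver transcripts into the wild type pool, but the largest excess there at the brightest probe sets of Alb, Afp and Apoa1 was 4.6 signal units, against 187.3 for Mt2. Lower glucocorticoid signalling would lower Fkbp5, Tsc22d3 and Per1, whose lowest log2 ratio was -0.18. Slc30a1, a zinc exporter induced by the metal-responsive factor MTF-1, was lower at both its probe sets (134.3 and 77.3, 40.0 and 29.5). It was picked after its values were seen. It therefore only prompted less metal-responsive transcription as a candidate explanation and is no test of it. Slc39a10, which that factor represses, had a log2 ratio of 0.14. That was in the predicted direction but smaller than the size set for it in advance, which leaves the explanation open. An effect of TAZ itself remains untested.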
